A study of Mus musculus with 6 samples.

How the data were processed

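RNA sequencing libraries from the pancreas of wild-type mice were compared between 3 saline-injected and 3 cerulein-injected samples. Cerulein is an analogue of cholecystokinin that overstimulates pancreatic acinar cells and is widely used to model acute pancreatitis. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with TRIzol, and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks the strand. The authors deposited raw read counts per gene as a single table with 36333 rows and 1 column per library. The submitters' processing notes name Trimmomatic, STAR, HTSeq and the mm10 build, without versions or settings. Whether counting used strand, which features were counted and which annotation release was used are not given in the sources used here. No column of other samples was present in the table.

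Total counts per library lay between 5335117 and 7610775. The deposited counts were used unchanged. Row names were matched to RefSeq genes of the GRCm38.p6 assembly, the assembly behind mm10, by symbol (32882 rows), gene ID (1378 rows) or a unique older symbol (939 rows), so that 35199 rows had a gene class and position. The unmatched rows held 0.214% of counts. Spreadsheet software had turned 12 symbols into dates, and these were left as they stood. A gene was taken as lncRNA by its RefSeq class, which gave 11108 rows. Strand and exons came from GENCODE. The mitochondrial genes of a list were matched by hand to the names used in the table.

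The counts carry a property that affects many genes. Of 809 protein-coding genes whose span lies wholly inside the span of another gene of the table, 776 (95.9%) were at 0 in all 6 libraries, against 27.8% of 14587 genes that overlap no other gene. For genes inside a gene on the other strand the share was 96.5% of 339, and among lncRNA genes inside another gene it was 98.2% of 2409, against 62.9% of 6327 lncRNA genes that overlap no other gene. Among the members of the gene lists, 27 of 29 inside another gene were at 0, against 6 of 574 others. A value of 0 for such a gene was therefore treated as no measurement. Reads of overlapping genes and of antisense partners may not be separable in these counts, and genes that partly overlap another may have lost reads. Near-identical copies, such as the amylase and alpha-globin genes, are uncertain in the same way.

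Genes were tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr filter, with a minimum count of 10 and a minimum total of 15, left 12441 genes, of which 418 were lncRNA and 11896 protein-coding. Library sizes were scaled with TMM factors, which were 1.03, 0.719 and 0.731 in saline replicates 1, 2 and 3 and 1.30, 1.13 and 1.26 in cerulein replicates 1, 2 and 3. The quasi-likelihood F test with robust shrinkage was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and a second count required a change of at least 2-fold. Standard errors of log2 fold changes were derived from the F statistics. CPM values are counts relative to the TMM-scaled library size, given as mean ± SD over 3 libraries. For a gene at 0 in a whole group, the fold was computed against a floor of 3 counts over the group. Ratios of counts carry exact 95% intervals, which cover counting error only, as reads without molecular identifiers are not independent molecules.

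A total of 28 gene lists were fixed before the data were examined. They cover digestive enzymes, acinar identity, secreted injury proteins, ductal markers, immediate early genes, ER chaperones, the ATF4 response, tRNA synthetases, NF-kB cytokines, markers of neutrophils, monocytes and macrophages, lymphocytes, islets, stellate cells and fibroblasts, endothelium, adipocytes and red blood cells, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, ribosomal proteins, ribosome biogenesis, autophagy and lysosome, heat shock proteins, antioxidant genes, cell death, cell cycle, YAP and cytoskeletal targets, and named lncRNAs. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry. Lists were adjusted over the 28 lists. Genes named in the text were chosen by a rule fixed in advance. The rule took the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1, groups that do not overlap and a named symbol. It added up to 4 members with the smallest p of each list, the 5 largest rises and falls among called lncRNA genes with an average log2 CPM of at least 0, and the cerulein receptor Cckar. Members beyond this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

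The comparison of library shares used a two-sided exact permutation test, which for 3 against 3 cannot give a p below 0.1. The replicate numbers were not used as pairs in the main test. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples. Replicates of a group differed by more than sampling noise, with a median chi-square per gene between 1.25 and 5.69, and none was counted as a repeat. The common biological coefficient of variation was 18.6%. The test was checked on simulated counts with the real means and library sizes over 12300 genes. For cerulein against saline it recovered 8.16% of genes changed 1.5-fold, 36.0% at 2-fold, 83.7% at 4-fold and 95.9% at 8-fold, with 6 false calls among 12100 unchanged genes. The simulation changed only 49 or 50 genes at each fold, against 6947 genes called in the real comparison. With so few changed genes the adjusted p cut-off is stricter, so these shares may understate recovery in the real data.

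Alternatives were the RLE and upper-quartile factors, library size alone, scaling without enzyme counts, no count filter, a filter of CPM above 1 in 3 libraries, no robust shrinkage, the replicate number as a block, each library left out, limma-voom and DESeq2 1.42.0. After the data were seen, lncRNA classes from GENCODE and a restriction to genes that overlap no other gene were added. The microRNA part of the ceRNA networks named in the study's title was not analysed here.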

Results

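The study set out to identify lncRNAs and mRNAs that change in the early stage of acute pancreatitis. RNA was sequenced from the pancreas of 6 wild-type mouse samples, 3 after intraperitoneal saline and 3 after cerulein. Cerulein was given 10 times in 200 µl at 200 µg/kg/h, and tissue was taken once the injections were complete. Total counts were 7194125, 6184013 and 5335117 in saline replicates 1, 2 and 3 and 6501212, 7610775 and 6307887 in cerulein replicates 1, 2 and 3. The first principal component held 81.2% of the variance and separated the groups. Saline replicates 1 and 2 lay farthest apart on the second, which held 9.01%.

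After cerulein, the digestive enzyme list and the cerulein receptor were lower, while the lists of ductal and metaplasia markers, YAP and cytoskeletal targets, immediate early genes, heat shock proteins, antioxidant genes and NF-kB cytokines were higher by camera with the preset correlation. With an estimated correlation no list was called. At the preset correlation the real split called 14 lists and the other splits of the 6 libraries 11 to 20. The number of lists called therefore does not set the real split apart. Each other split mixes saline and cerulein libraries unequally, so part of the cerulein difference remains between its groups. Such splits do not show how many lists groups without a difference would call. Digestive enzyme genes took 57.9% ± 7.97 (SD, n = 3) of all counted reads in saline and 32.8% ± 2.27 (SD, n = 3) in cerulein, a difference of -25.1 percentage points (exact permutation test, two-sided p = 0.1, the smallest possible). The enzyme share was 48.7% in saline replicate 1, against 62.0% and 62.9% in saline replicates 2 and 3. These shares leave out the trypsinogen genes, which were at 0 in all libraries and are treated as not measured. Of 12441 genes tested, 3574 (28.7%) were called higher and 3373 (27.1%) lower, and 2273 and 2206 of these changed at least 2-fold. Counts of calls within the gene lists below are to be read against these shares. The groups did not overlap for 7836 genes, or 63.0%, where chance gives 10% for 3 against 3. The split into higher and lower calls depended on scaling. It was 2895 higher and 4190 lower with upper-quartile factors, and 5181 higher and 1449 lower with library size alone, which moved the median log2 fold change of all genes by -0.197 and 0.565. Genes changed at least 2-fold numbered 1800 higher and 2762 lower with upper-quartile factors, and 4001 and 1072 with library size alone. Changes below are relative to the TMM scaling.

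**Figure D1:**
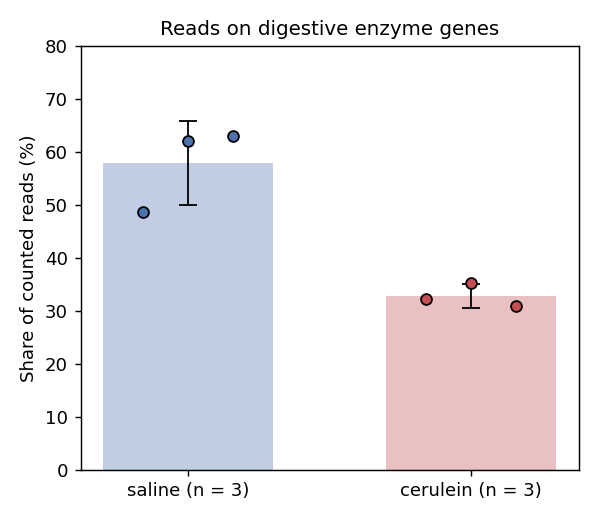
Share of counted reads on digestive enzyme genes, in percent, for 3 saline and 3 cerulein libraries, with points for libraries, bars for group means and error bars for the SD. The saline libraries lay between 48.7% and 62.9%, and the cerulein libraries between 30.8% and 35.3%.

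Of 23 digestive enzyme and cofactor genes tested, 21 fell, none rose and 2 did not pass the threshold, and 22 fell when adjusted over the list alone. The median log2 fold change was -1.97. Ctrc, the chymotrypsin C gene, which RefSeq lists as a transcribed pseudogene in this assembly, fell from 981 ± 283 to 42.5 ± 5.78 CPM (SD, n = 3 each), a log2 change of -4.53 ± 0.26 (SE, adjusted p = 2.89e-08, edgeR). The salivary-type amylase gene Amy1 fell by 2.35 ± 0.18 and the elastase gene Cela3a by 2.81 ± 0.23 on the log2 scale. The pancreatic amylase copies differed in size of change, with -7.05 ± 0.30 for Amy2a5 and -2.05 ± 0.28 for Amy2b, the latter chosen after its values were seen. These copies lie close together on chromosome 3 and are near-identical, so the split of reads among them is uncertain. The members not past the threshold, Ctrb1 and Sycn, had log2 fold changes of -0.75 ± 0.31 and -0.32 ± 0.33. Without saline replicate 1 both passed, at -0.94 and -0.65. Ctrb1 also passed with upper-quartile factors, limma-voom and DESeq2, and Sycn was at 0.32 with library size alone. The list was lower by camera (adjusted p = 1.68e-11), with adjusted p = 0.421 with an estimated correlation. The trypsinogen genes Prss1, Prss2, Prss3, Try4, Try5 and Try10 lie inside the span of Tcrb on chromosome 6 and were at 0 in all 6 libraries, which was treated as no measurement.

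Among 15 acinar identity genes, 10 fell and 3 rose, and the counts were the same when adjusted over the list alone. Cckar, the cholecystokinin receptor at chromosome 5, 53698485 to 53707704 (mm10), fell from 609 ± 157 to 11.5 ± 1.86 CPM (log2 change -5.72 ± 0.27, adjusted p = 9.70e-09, edgeR). Rbpjl, a subunit of the acinar PTF1 transcription complex, fell by 2.89 ± 0.22 and Nr5a2, a nuclear receptor of acinar cells, by 1.55 ± 0.18 on the log2 scale. Ptf1a, the master regulator of acinar fate, was among the 3 that rose, at 1.38 ± 0.24, and is named after its value was seen. The list was lower by camera (adjusted p = 0.00152), with adjusted p = 0.628 with an estimated correlation.

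Of 14 secreted injury proteins tested, 5 rose and 7 fell, both over all genes and adjusted over the list alone. Clu, encoding the chaperone clusterin, rose by 2.17 ± 0.23 on the log2 scale, to 4707 ± 810 CPM, and the annexin gene Anxa2 by 3.37 ± 0.23. All 6 tested Reg genes, which encode secreted lectin-like proteins, were lower, under each scaling tried. The log2 fold change was -4.09 ± 0.26 for Reg3d and -7.17 ± 0.94 for Reg3a (adjusted p = 6.97e-08 and 9.82e-04, edgeR). Reg3a stood at 1601 CPM in saline replicate 1 against 289 and 381 CPM in saline replicates 2 and 3, and without saline replicate 1 its log2 fold change was -6.02. The list as a whole did not pass camera (adjusted p = 0.425).

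Ductal and metaplasia markers rose for 11 of 15 genes and fell for 2, with the same counts adjusted over the list alone and a median log2 fold change of 2.81. The median was 1.44 without a count filter, 2.12 with the filter of CPM above 1 in 3 libraries, 2.12 and 2.01 without saline replicate 2 or 3, and 2.15 without cerulein replicate 3, where more members are tested. Krt8, an epithelial keratin at chromosome 15, 101996711 to 102004342, went from 157 ± 21.5 to 5945 ± 508 CPM (log2 change 5.24 ± 0.26, adjusted p = 1.22e-08, edgeR). Its partner Krt18 rose by 4.24 ± 0.26, and the ductal keratins Krt19 and Krt7 by 4.89 ± 0.25 and 3.90 ± 0.21. Among those that fell was Muc1, an epithelial mucin gene, with -1.40 ± 0.17, named after its value was seen. YAP and cytoskeletal targets rose for 14 of 19 genes, or 16 adjusted over the list alone, and none fell. The beta-tubulins Tubb6 and Tubb2a rose by 4.47 ± 0.24 and 4.36 ± 0.22, and Actb, encoding beta-actin, by 3.38 ± 0.25, from 390 ± 97.0 to 4064 ± 432 CPM. Both lists were higher by camera (adjusted p = 9.85e-09 and 2.07e-10), with adjusted p = 0.188 and 0.102 with an estimated correlation.

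Immediate early genes were higher for 23 of 25 genes and lower for none, with the same count adjusted over the list alone, and 1 was lower without saline replicate 1. Atf3, a stress-induced transcription factor, rose by 5.46 ± 0.21 on the log2 scale, from 6.95 ± 1.37 to 304 ± 10.8 CPM (adjusted p = 4.89e-09, edgeR), and Ier5 and Ier3 rose by 4.06 ± 0.17 and 3.90 ± 0.18. Heat shock genes rose for 14 of 15, including the chaperone genes Hsp90aa1 at 4.07 ± 0.23 and Dnajb1 at 2.61 ± 0.15. Antioxidant genes rose for 14 of 16. Srxn1, encoding sulfiredoxin, rose by 5.62 ± 0.27 and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, by 4.73 ± 0.25. The ATF4 and integrated stress response list rose for 16 of 19 genes, with Ppp1r15a, a phosphatase subunit that restores translation, at 2.54 ± 0.17 and the transcription factor Cebpb at 3.14 ± 0.22. None of these 3 lists had a member that fell, except 1 antioxidant gene with upper-quartile factors, and their counts were unchanged when adjusted over the list alone. All 4 lists were higher by camera (adjusted p = 1.20e-16, 1.09e-12, 1.15e-08 and 6.92e-08). With an estimated correlation the adjusted p was 0.0675 for immediate early genes and 0.265 for each of the other lists.

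Of 23 ER chaperone and ERAD genes, 14 fell and 3 rose, both over all genes and adjusted over the list alone, and the median log2 fold change was -0.78. Sel1l, a core component of ER-associated degradation, fell from 1790 ± 170 to 129 ± 26.5 CPM (log2 change -3.79 ± 0.23, adjusted p = 4.08e-08, edgeR), and the co-chaperone genes Dnajb11 and Dnajc3 fell by 1.94 ± 0.17 and 1.98 ± 0.18. The genes that rose were Hspa5, encoding the main ER chaperone BiP, at 1.49 ± 0.24, Dnajb9 at 0.64 and Calr at 0.61, named after their values were seen. The list was lower by camera (adjusted p = 9.62e-04), with adjusted p = 0.640 with an estimated correlation. With library size alone, 8 members were lower and 6 higher, and without cerulein replicate 3 only 1 was higher. Dnajb9 lost its call there, as did Calr, which also lost it without saline replicate 1, saline replicate 3 or cerulein replicate 2 and with upper-quartile factors.

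Mitochondrially encoded genes fell for 12 of 13 and nuclear oxidative phosphorylation genes for 23 of 32, none rose in either list, and the counts were the same adjusted over the list alone. ND5 and ND1, subunits of complex I, fell by 1.30 ± 0.21 and 1.13 ± 0.19, and the nuclear complex I genes Ndufs3 and Ndufv2 by 2.10 ± 0.21 and 1.66 ± 0.19 on the log2 scale. The medians were -0.83 and -0.84, and camera gave adjusted p = 0.00454 and 1.42e-04, with adjusted p = 0.640 and 0.544 with an estimated correlation. With library size alone the medians were -0.21 and -0.28, with 2 and 9 members lower and 0 and 4 higher. Mitochondrial transcripts took 2.72% ± 0.0653 of counts in saline and 2.34% ± 0.164 in cerulein (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible).

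The NF-kB list, which holds cytokines, chemokines and other genes of the pathway, rose for 23 of 23 tested genes, also adjusted over the list alone. The median log2 fold change was 2.76. With upper-quartile factors 22 were called higher, and without a count filter 21 of 26 were. Lif, a cytokine of the interleukin 6 family, rose by 5.70 ± 0.29 on the log2 scale (adjusted p = 1.51e-08, edgeR). Il1b rose by 4.33 ± 0.28 and Relb, an NF-kB subunit, by 2.59 ± 0.19. The list was higher by camera (adjusted p = 1.09e-12), with adjusted p = 0.190 with an estimated correlation. Il6, Cxcl10, Csf1 and Csf2 lie inside other genes and were at 0. Cell death genes rose for 13 of 21 and fell for none, also adjusted over the list alone, and 1 fell without saline replicate 1 or with upper-quartile factors. They included Tnfrsf12a, a TWEAK receptor, at 5.23 ± 0.25, and the survival genes Bcl2l1 and Mcl1 at 3.06 ± 0.20 and 1.99 ± 0.17, which act against cell death. That list was higher by camera (adjusted p = 9.31e-04), with adjusted p = 0.265 with an estimated correlation.

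Of 15 monocyte and macrophage markers, 6 rose and 1 fell, also adjusted over the list alone, with Cd14 at 2.81 ± 0.29 and Ccr2, a monocyte chemokine receptor, at 2.33 ± 0.32, and the list did not pass camera (adjusted p = 0.268). The median of that list, 0.09, lay between -0.11 without cerulein replicate 1 and 0.29 without saline replicate 1, and was -0.08 without saline replicate 2, where 3 markers were lower. None were lower without saline replicate 1, cerulein replicate 2 or cerulein replicate 3 or with library size alone, and 2 were with upper-quartile factors. Neutrophil markers were called higher for 2 of 11, or 1 adjusted over the list alone, with Trem1 at 2.10 ± 0.31. The other, Clec4d at 1.28, lost its call without saline replicate 3 or cerulein replicate 3. Their summed level was 260 CPM in saline replicate 1 against 30.2 and 51.9 CPM in saline replicates 2 and 3, and 113 ± 40.4 CPM in cerulein. Without saline replicate 1, 6 neutrophil markers were higher and the median log2 fold change was 1.97 in place of -0.08. Leaving out another library gave medians from -0.48, without cerulein replicate 3, to 0.18, without cerulein replicate 1, and limma-voom gave 0.52. None were called lower, but 1 was in most of the alternatives, among them those without saline replicate 2, saline replicate 3 or cerulein replicate 3. The neutrophil list did not pass camera (adjusted p = 0.643), and its direction there was up while its median and mean were below 0. Of 14 lymphocyte markers, 1 rose and none passed when adjusted over the list alone (camera adjusted p = 0.731). The median, 0.13, was 0.97 without saline replicate 1, -0.35 without saline replicate 2 and -0.24 without cerulein replicate 1, and between 0.27 and 0.41 without each other library. That gene, Ltb, had an adjusted p of 0.0146 and lost its call without cerulein replicate 1.

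Islet markers fell for 7 of 19 and rose for 1, or 6 and 1 adjusted over the list alone, and with library size alone 1 fell and 4 rose. Slc30a8, the zinc transporter of insulin granules, fell by 2.28 ± 0.32, whereas the insulin genes Ins1 and Ins2, named after their values were seen, had log2 fold changes of 0.03 ± 0.34 and -0.03 ± 0.37, signs that changed with the scaling and with the library left out, and Ins1 passed with library size alone. The number of islet markers that fell was 11 without saline replicate 1, 3 without saline replicate 3, and 4 without cerulein replicate 2 or cerulein replicate 3, with 3 higher in the last case. Stellate cell and fibroblast markers rose for 6 of 16 and fell for 1, also adjusted over the list alone, with the collagen genes Col1a1 and Col3a1 at 1.08 ± 0.24 and 0.71 ± 0.16, and with library size alone 11 rose and none fell. Endothelial markers rose for 2 and fell for 2 of 14, or 2 and 1 adjusted over the list alone, with a median of 0.07, a mean of -0.04 and camera pointing down. The balance of these calls moved with the scaling, with 0 higher and 4 lower with upper-quartile factors, where Eng and Esam were lost, and 6 higher and 0 lower with library size alone, where Kdr and Vwf were lost. Leaving out cerulein replicate 2 ended the call of Eng, cerulein replicate 3 that of Kdr, and each library except saline replicate 1 and cerulein replicate 1 that of Vwf. The endothelial median was -0.01 without saline replicate 2 and -0.09 without cerulein replicate 1, and at most 0.10 without any other library, and 4 markers rose without cerulein replicate 3. Adipocyte markers rose for 1 and fell for 2 of 8, also adjusted over the list alone, with Fabp4 at -1.29 ± 0.18. None of 4 red blood cell markers passed, in edgeR or adjusted over the list alone. Camera gave adjusted p = 0.268 for islet, 0.423 for stellate, 0.870 for endothelial, 0.433 for adipocyte and 0.640 for red blood cell markers. The adipocyte median, -0.60, was 0.05 without saline replicate 1, where 2 markers rose, -1.04 without saline replicate 2 or 3, and -1.11 without cerulein replicate 1, where 3 fell. The red blood cell median, -0.83, was -0.11 without saline replicate 3 and -1.29 without saline replicate 1, where 3 markers were lower.

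Genes of ribosome biogenesis rose for 23 of 30 and fell for 2, with the same counts adjusted over the list alone, and 1 fell without saline replicate 2 or 3, or cerulein replicate 1 or 2. Nop2 and Rrp12, which act in ribosomal RNA processing, rose by 1.37 ± 0.17 and 1.67 ± 0.21. The list was higher by camera (adjusted p = 9.83e-04), with adjusted p = 0.640 with an estimated correlation. Cytosolic ribosomal protein genes rose for 8 of 35 and fell for 1, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.640), with Rpl27 at 0.77 ± 0.20. With library size alone 25 of them were higher, and with upper-quartile factors 4 were higher and 4 lower. Without saline replicate 2 or 3, or cerulein replicate 2 or 3, 5 were higher. Without saline replicate 1, 2 were lower, and without saline replicate 3, or cerulein replicate 1 or 3, none were. The median, 0.12, lay between -0.02, without saline replicate 1 or cerulein replicate 2, and 0.22, without cerulein replicate 1 or 3. The tRNA synthetase genes rose for 9 of 18 and fell for 2, also adjusted over the list alone, with Nars at 1.72 ± 0.18 and Rars at 1.45 ± 0.17 (camera adjusted p = 0.142). With upper-quartile factors 4 of these fell, with library size alone none did, and without cerulein replicate 1 it was 1. Autophagy and lysosome genes rose for 10 of 23 and fell for 4, also adjusted over the list alone (camera adjusted p = 0.149). Sqstm1, the autophagy receptor p62, rose by 3.33 ± 0.23, and the protease gene Ctsl by 1.85 ± 0.20. Cell cycle genes rose for 3 of 11 and fell for none, also adjusted over the list alone (camera adjusted p = 0.520), led by Mcm6 at 1.34 ± 0.23. The others, Mcm7 and Rrm2, lost their calls without cerulein replicate 2, and Rrm2 also without saline replicate 1 and with upper-quartile factors. With library size alone, 16 autophagy genes were higher and 1 lower, and 6 cell cycle genes were higher, and with upper-quartile factors 7 autophagy genes were higher and 6 lower.

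**Figure D2:**
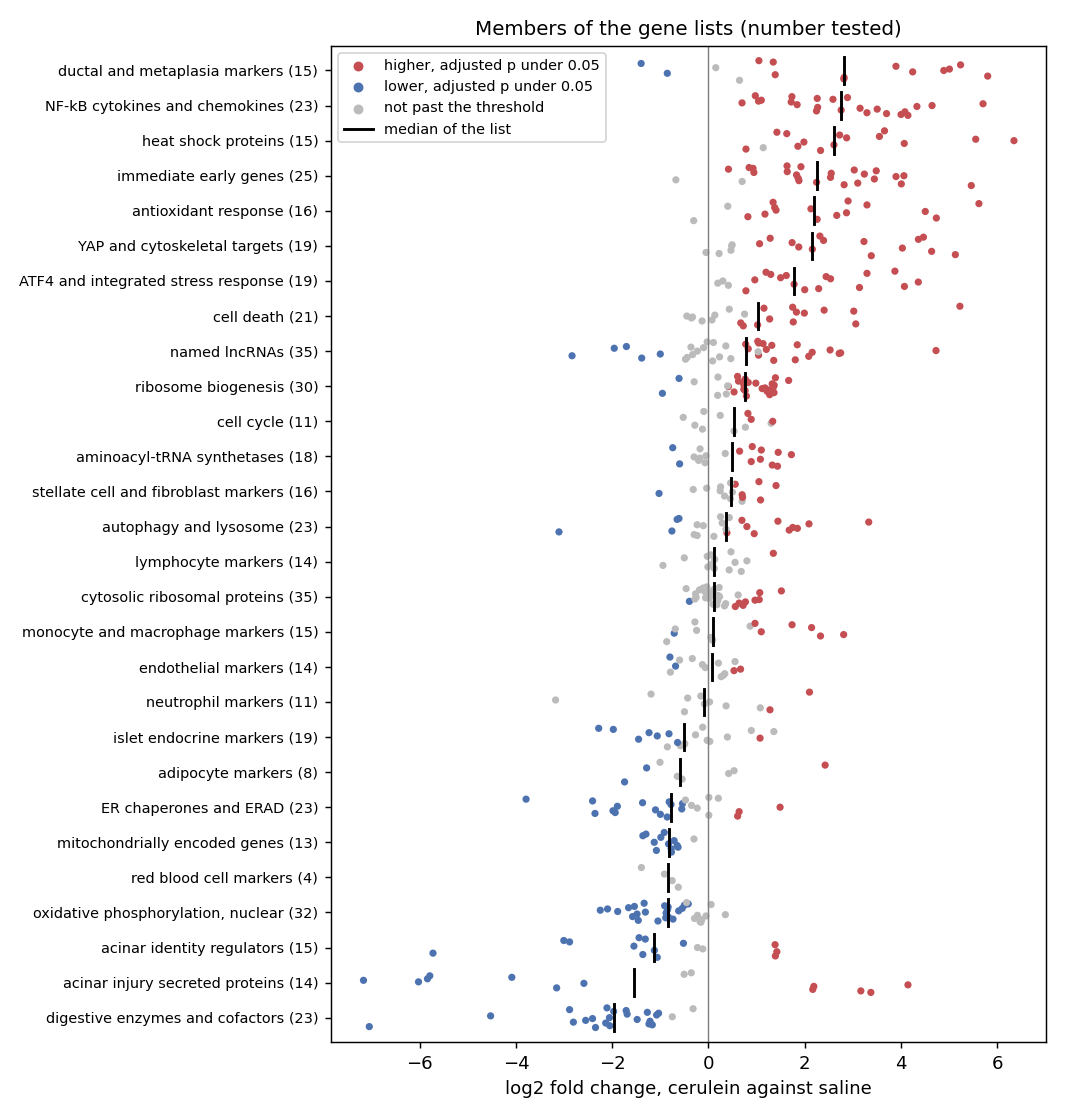
The log2 fold change of each tested gene after cerulein against saline (x axis), by gene list (y axis, with the number tested), where red points are called higher, blue points called lower, grey points are not past the threshold and black lines are list medians. Medians run from -1.97 for digestive enzymes to 2.81 for ductal and metaplasia markers, a median that is 1.44 without a count filter. With library size alone every median lies higher, the islet and neutrophil medians turn positive, and with upper-quartile factors the medians of lymphocyte, monocyte, endothelial and ribosomal protein genes turn negative.

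The largest single rises were in genes close to 0 in saline. Ppef1, a calcium-binding protein phosphatase gene at chromosome X, 160622419 to 160751290, had 1 count over the saline libraries and 1897 over the cerulein libraries, a ratio of 1196 (exact 95% interval 214 to 47275). Tac1, encoding substance P, a neuropeptide, had no saline count and 428 counts over the cerulein libraries. Crct1 and Anxa10, both at 0 in saline, were at least 34.7-fold and 34.3-fold higher. Krt17, a keratin of injured epithelia, had a ratio of 349 (62.4 to 13824). The blood group gene Kel, at chromosome 6, 41686329 to 41704334, rose from 1.53 ± 0.561 to 296 ± 56.6 CPM (log2 change 7.49 ± 0.29, adjusted p = 4.89e-09, edgeR). Sprr1a, Prss56, Aloxe3 and Nrip3 completed the 10 largest rises, with ratios of 175, 179, 132 and 100.4. The fitted log2 fold change of Sprr1a was 7.35, 6.46 without saline replicate 1 and 9.34 without saline replicate 3, and that of Prss56 was 7.11, 6.33 without saline replicate 1 and 9.37 without saline replicate 2. Without saline replicate 1, which held their only saline count, Ppef1 and Krt17 were at 0 in saline. Prss56 was at 0 in saline without saline replicate 2, so its value there was fitted against a group without counts.

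Among the largest falls, Sostdc1, a secreted antagonist of bone morphogenetic proteins, fell from 146 ± 52.7 to 0.865 ± 0.662 CPM (log2 change -7.33, adjusted p = 6.15e-06, edgeR). Vmn2r9, Cyp4f15, Agtr1b and Slc10a5 were at 0 in all cerulein libraries and were at least 154-fold, 89.3-fold, 35.4-fold and 34.9-fold lower. The largest falls also included Reg3a and the amylase copies Amy2a3, Amy2a4 and Amy2a5, for which counting between copies is uncertain. The fitted log2 fold change of Amy2a3 was -8.32, and -10.68 without cerulein replicate 3, which held its only cerulein counts, and that of Amy2a4 was -7.08, and -7.82 without cerulein replicate 2.

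**Figure D3:**
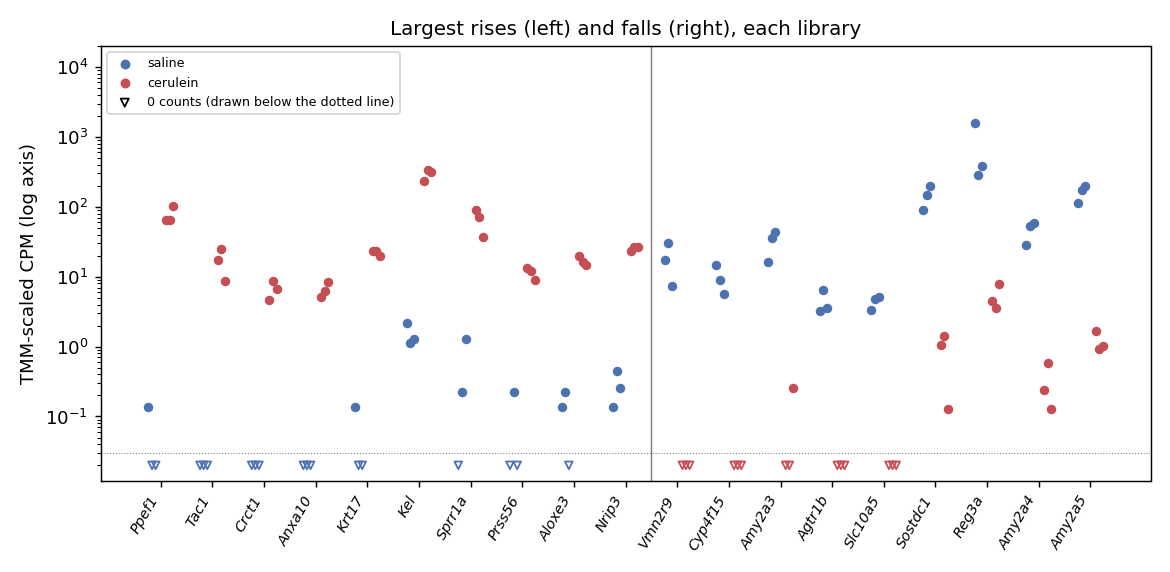
TMM-scaled CPM on a log axis for the 10 largest rises and 9 of the 10 largest falls in each of 3 saline and 3 cerulein libraries, where open triangles below the dotted line are libraries with 0 counts. Kel stood between 232 and 341 CPM in cerulein and between 1.13 and 2.17 CPM in saline, and Reg3a was highest in saline replicate 1.

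For lncRNAs, 101 of 418 tested genes were higher and 148 lower after cerulein, and 91 and 138 of these changed at least 2-fold. Over all 12441 genes tested, 28.7% were higher and 27.1% lower, and no test set the lncRNA shares against these. The balance of higher and lower calls moved with the scaling, as library size alone gave 145 higher and 106 lower, and 129 and 100 at least 2-fold. Neat1, the scaffold RNA of nuclear paraspeckles at chromosome 19, 5824708 to 5845480, rose from 856 ± 111 to 3814 ± 300 CPM (log2 change 2.16 ± 0.22, adjusted p = 2.83e-06, edgeR). Of 35 named lncRNAs tested, 17 rose and 5 fell, or 17 and 7 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.156). The microRNA host genes Mir22hg and Mir17hg rose by 2.75 ± 0.20 and 2.72 ± 0.22, Firre, an X-linked nuclear RNA, fell by 1.39 ± 0.15, and Malat1, named after its value was seen, had a log2 fold change of -0.33 ± 0.36, which was 0.23 without saline replicate 2 and 0.28 with library size alone. The largest rises were 1700016G22Rik, Gm34642, Gm9926 and Gm36806, at 0 in saline and at least 145-fold, 70.0-fold, 32.4-fold and 14.7-fold higher, and Gm30963 with a ratio of 156 (60.8 to 575). Of these, 1700016G22Rik, Gm34642 and Gm30963 lay within 20 kb of the 5' ends of Klf6, Trpv6 and Uhrf1bp1l, each called at least 2-fold higher. Gm9926 and Gm36806 had no such neighbour with a known strand. Whether these lncRNAs rose apart from their neighbours was not tested. The largest falls were Gm30723, at 0 in cerulein and at least 25.9-fold lower, LOC108167736, B230206L02Rik and Gm34470, each with 1 to 3 counts in cerulein, and 1810018F18Rik, which fell from 356 ± 123 to 6.42 ± 1.45 CPM (log2 change -5.79 ± 0.31) and is classed as a pseudogene by GENCODE. The fitted log2 fold change of Gm30963 was 7.19, and 8.13 without saline replicate 1. Those of LOC108167736 and Gm34470 were -6.17 and -5.84, and -6.94 and -7.43 without cerulein replicate 2, and that of B230206L02Rik was -5.93, and -7.55 without cerulein replicate 3. The libraries left out held the only cerulein count of Gm34470 and of B230206L02Rik, so those values were fitted against a group without counts. Of the 249 called lncRNAs, 111 partly overlapped another gene and 7 lay inside one, so their counts may not be separable from the neighbour. With only genes that overlap no other gene, an alternative chosen after seeing the data, 55 lncRNAs were higher and 76 lower. With GENCODE classes, also chosen after seeing the data, 62 were higher and 108 lower, and without a count filter 199 were higher and 342 lower.

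**Figure D4:**
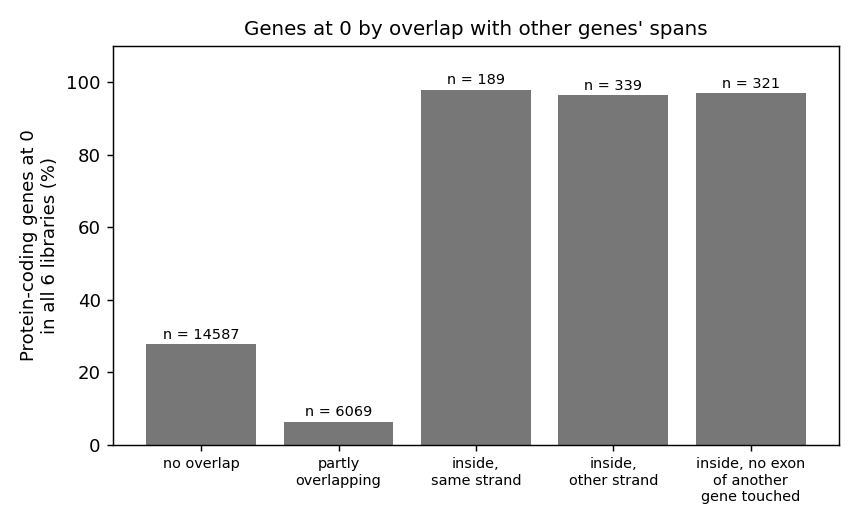
Percent of protein-coding genes at 0 in all 6 libraries (y axis) by how their span overlaps other genes of the table (x axis), with the number of genes above each bar. Genes inside another gene's span were at 0 in 97.9% of cases on the same strand and 96.5% on the other strand, against 27.8% of genes without overlap and 6.31% of those partly overlapping.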

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

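The alternatives were chosen before the data were examined, except the GENCODE classes and the restriction to genes that overlap no other gene, which were chosen after seeing the data. Of 163 genes, 141 taken by the rule for named genes and the others named outside it, 146 were called. None of these turned under any alternative, and 15 lost the call under at least 1. The rule takes large changes and small p-values of the main test, so this says little about calls outside these genes. The log2 fold changes of 5 genes not past the threshold turned, namely Hba-a1, Ins1, Ins2, Malat1 and Sycn. Hba-a1 was at 0.0368, Ins2 at 0.64, Malat1 at 0.28 and Sycn at 0.32 with library size alone, and Ins1 at -0.16 with upper-quartile factors. Ins2 was at 0.0455 without a count filter, 0.062 with the replicate block and 0.0306 with limma-voom. Leaving out each library gave -1.10 to 0.16 for Hba-a1, -0.31 to 0.26 for Ins1, -0.40 to 0.19 for Ins2 and -0.62 to 0.23 for Malat1. The cause of these turns was not tested. With library size alone, 1449 genes were lower, 4001 at least 2-fold higher and 1072 at least 2-fold lower, and the TMM factors are then absent by construction. How far those factors reflect the difference in enzyme content was not tested. Without a count filter, 199 lncRNAs were higher and 342 lower, as more genes enter the test. With an estimated correlation, camera called 0 lists higher and 0 lower, against 9 and 5 with the preset one, while fry, which does not compare a list with other genes, called 12 and 5. With GENCODE classes, 62 lncRNAs were higher. With genes that overlap no other gene, 2369 genes were higher, 2102 lower, 1359 at least 2-fold lower, and 55 lncRNAs higher and 76 lower, as fewer genes are counted. Leaving out each library gave 3112 to 3692 genes higher and 2911 to 3552 lower, and an enzyme share difference of -29.6 to -22.5 percentage points. A pairing of the samples by replicate number was not shown. The deviations of samples 1, 2 and 3 correlated at 0.19, 0.216 and -0.15 across groups. Those numbered 1 and those numbered 2 correlated best with each other, but those numbered 3 did not, so these values do not decide it. With a replicate block, 3673 genes were higher and 3401 lower, 2320 and 2192 at least 2-fold, 104 and 152 lncRNAs, and 9 and 5 lists. Within lists, the block called 2 adipocyte markers higher and 4 lower, 2 lymphocyte and 5 cell cycle genes higher, 1 neutrophil marker lower, and 9 ribosomal protein genes higher and 2 lower. At this depth and with 3 libraries per group, simulated 1.5-fold changes were recovered in 8.16% of cases. That simulation changed far fewer genes than the 6947 called here, so it may understate recovery. Genes not called may still have changed by that size, but how many were missed is not known.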

Other observations

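Several genes outside the lists, chosen after their values were seen, also changed strongly. Rcan1, an inhibitor of calcineurin that calcium signalling induces, rose from 36.5 ± 14.2 to 2533 ± 340 CPM (log2 change 6.13 ± 0.32, adjusted p = 1.51e-08, edgeR), and Hbegf, a ligand of the EGF receptor, rose by 5.02 ± 0.25. The log2 fold change was -5.98 ± 0.48 for the sterol exporter gene Abcg8, and -5.56 ± 0.33 and -5.46 ± 0.28 for the tight junction genes Cldn8 and Cldn10. Trpv6, a calcium channel gene, and the lncRNA Gm34642 lie near Kel between positions 41620619 and 41704334 of chromosome 6, and all 3 rose. Cdk8, also chosen after its values were seen, did not pass the threshold, with a log2 fold change of 0.79 ± 0.32 (adjusted p = 0.0521, edgeR), but passed with library size alone, without a count filter, with the filter of CPM above 1 in 3 libraries, without saline replicate 2, with limma-voom and with DESeq2. It held 1.07% ± 0.365 of counts in saline and 2.72% ± 0.682 in cerulein (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest possible), and whether reads of other transcripts inside its span add to this share was not tested.

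The following tests were chosen after the results were seen, except the neighbour test of 64 genes, the median of intestinal markers and the splits of the samples, which were written down before their results were seen. Genes inside another gene's span were at 0 far more often than other genes. Silence of such genes in the pancreas is argued against by the list members, which were picked without regard to position: 93.1% of those inside another gene were at 0 against 1.05% of the others (Fisher's exact test, p = 7.40e-39). Counting over exons is argued against by the inside genes that touch no exon of another gene, 96.9% of which were at 0. The share of 96.5% for genes inside a gene on the other strand is consistent with counts taken over whole gene spans without strand, with reads in more than 1 span dropped. Under that hypothesis intron reads may enter the counts too, which was not tested.

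A group of 64 called genes with a saline mean below 1 CPM had a fitted rise of at least 16-fold. Transcription that runs on within 20 kb past the 3' end of a gene called at least 2-fold higher was considered as a source. Only 4 of the 64 lay that close to such an end, among neighbours with a known strand and no overlap. Run-on from overlapping neighbours or from those without a known strand was not tested. Within 20 kb of the 5' end of such a gene lay 14. Near only a 3' or only a 5' end were 3 and 13 (exact sign test, p = 0.0213, or 0.0425 adjusted over 2 tests of neighbours). The excess near 3' ends predicted for run-on was thus not seen. The excess near 5' ends does not itself speak against run-on, and its cause was not tested. The other test decides nothing: for the 71 of 341 genes called at least 4-fold higher, at 50 CPM or more in cerulein, with tested genes that close on both sides, the log2 fold change of the 3' neighbour minus that of the 5' neighbour averaged -0.232 (permutation test, two-sided p = 0.374, also after adjustment). Counting noise alone is argued against for genes with at least 30 counts, whether called or not. Of 13663 such genes, 94 met these bounds on pooled counts, where binomial sampling without a change gives 0.00140. Among 6893 genes with fewer counts, 1816 met them, against 1553 from sampling. Of the 64, 63 are among the 94, but the 64 had already passed the call, so that was close to fixed in advance. The binomial model leaves out the spread between libraries beyond sampling. A response to cerulein stays open as a hypothesis, found and tested on the same data, and so does a change in the cells present.

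The Reg genes fell although they are widely described as induced in pancreatitis. Among the saline libraries, replicate 1 had the highest Reg2, Reg3a, Reg3b, Reg3d and Reg3g and the lowest Reg1, but without it the median log2 fold change of 6 Reg genes was -5.20, against -5.81 with it. Leaving enzyme counts out of the scaling gave -5.83 but decides nothing, as it moved the median of all genes by only -0.0174, whereas with library size alone, which moved that median by 0.565, the Reg median was -5.35 and 6 of 6 were called lower. Intestinal tissue in the saline libraries was a candidate source, and its 4 tested markers had a median of -1.07, just past the bound of -1 written in advance; with 4 of 18 markers tested and 2 lower, 1 higher and 1 not past the threshold, that test is void. In a test chosen after that result, 12 of 17 markers not inside another gene had 3 counts or fewer over the saline libraries, and Fabp1, Apoa1, Apoa4 and Sis had 0, which argues against intestinal tissue, and the state of the saline animals stays open.

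With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 6947 genes, 4479 at least 2-fold and 249 lncRNAs, each reached by 1 of the 10 splits, and the highest other split called 0 in each case with edgeR. Each other split mixes saline and cerulein libraries in both groups, which adds the cerulein difference to the spread within groups. Calls of 0 there therefore do not show what groups without a difference would give. For the gene lists, 6 of the 10 splits, the real one included, called at least as many lists by camera with the preset correlation. The real split called 14, the highest other split 20 and the lowest 11, so the number of lists called does not set the real split apart. The other splits keep part of the cerulein difference between their unequally mixed groups, so they do not decide about the lists either.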
